A study of Homo sapiens with 24 samples.

How the data were processed

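Messenger RNA was sequenced from H9 cells, an established human embryonic stem cell line, in 24 libraries: 8 groups of 3. Monocultures held either cells carrying the light-responsive receptor construct (Cry2) or wild-type cells (wt), each kept in the dark or under light. Co-cultures held both kinds of cell together, in the dark or under light, and were sorted into mCherry-positive cells, which carry the construct, and GFP-positive wild-type cells. Per the labels' protocols, light was given at 0.8 µW/mm² for 48 h, each biological replicate pooled 2 to 3 wells, and libraries were made with a kit that keeps strand information; the strand setting of the counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

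Per the submitters' processing notes, the reads went through FastQC, cutadapt, Bowtie2, STAR, HTSeq and DESeq, with versions not given in the sources used here. Those notes name GRCh38, while the header of the authors' sample table says that reads were aligned to hg19 with 4 extra genes after mitochondrial, ribosomal, transfer RNA and repeat reads were removed. The conflict was not resolved, and every coordinate printed here comes from GENCODE 29 on GRCh38, looked up by Ensembl identifier. The authors' deposited gene table holds a normalised expression signal for 28301 features: 28297 Ensembl genes and 4 construct features (the Cry2 fusion with mCherry, eGFP and the puromycin and neomycin resistance genes). Of the Ensembl genes, 27908 matched a reference name, 46 names were shared by 148 features, and the lowest sum of a feature over all libraries was 10 reads, so silent genes had been left out. The authors' deposited sample table gives total read counts, the percent of GC and of aligned reads, and the RNA integrity number, a score, for the 12 monoculture libraries.

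The deposited signal turned out to be read counts divided by 1 factor per library: after multiplication by each library's own factor, 100.0% of values were whole within 0.01. Depth, as reads assigned to genes and recovered in this way, ran from 28237578 to 56639833 reads per library. The 3 monoculture dark libraries of each genotype were shallower than the 3 light libraries, so depth and light coincide in monoculture; the third library (c) of each co-culture light group, with 31807414 reads in mCherry and 31884623 reads in GFP, was shallower than the other 2. Intervals and floors given below cover counting error only.

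Monoculture samples were matched to columns by the column name given in each sample's description. For the co-culture columns the authors' sample table gave only the group, so those libraries are called a, b and c in column order and were not paired in the main tests. In the monoculture labels the genotype tags name the opposite genotype from the titles; the titles were used, and they go with the authors' sample table and with the construct reads. Among the 24 pairs of libraries within groups, read counts differed by 4.36 to 78.62 times the chi-square expected from counting noise per degree of freedom, so no library was counted as a duplicate. The largest values were those of mCherry light a (68.91 and 78.62) and of wt light replicate 2 (56.79 and 46.7) against the other libraries of their groups.

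Design, gene lists, named-gene rule and most alternative settings were fixed before the data were examined. The main test, planned for normalised values, was limma-trend 3.58.1 in R 4.3.3 on log2(value + 1), with genes at a value of at least 10 in at least 3 libraries of the fit and Benjamini-Hochberg adjusted p under 0.05. The 12 monoculture libraries were fitted together (19444 genes), as were the 12 co-culture libraries (19436 genes); differences of light effects between the cultures used all 24 (20322 genes). Construct features were left out of the gene tests. Log2 changes carry the pseudocount and so understate changes of weakly expressed genes; folds are ratios of group means. A fold against a group without reads is a lower bound against a floor of 3 counts over the group, and none is given against a group with 1 to 3 reads. LRP6 shares sequence with the construct, so its reads are uncertain; it was tested by an exact two-sided permutation test within each culture.

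For each comparison the text could name LRP6; 25 genes chosen beforehand (always for light against dark in engineered cells, elsewhere only if past the threshold); the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a mean of at least 50 in the higher group, a symbol, and no overlap between groups; up to 4 members per direction of a described list; and, where fewer than 20 genes passed, all of them. Other genes are marked as chosen after their values were seen. The 26 lists, written from textbook knowledge, covered Wnt/beta-catenin feedback and target genes, Wnt ligands, the BMP, NODAL/TGF-beta, FGF/ERK and Notch pathways, Eph receptors and ephrins, primitive streak and mesendoderm, paraxial and posterior mesoderm, lateral and cardiac mesoderm, definitive endoderm, neural ectoderm, neural crest, amnion and surface ectoderm, endothelium and blood, germ cell, pluripotency, naive pluripotency, epithelial junction, mesenchymal and epithelial-mesenchymal transition (EMT) genes, proliferation, p53 targets, immediate early and heat shock genes, oxidative stress, hypoxia and glycolysis, and the unfolded protein and amino acid response. Each was tested with limma's camera (two-sided, preset correlation 0.01) and again with an estimated correlation, and p was adjusted over the 208 tests of 26 lists in the 8 comparisons of 2 groups; the 4 differences of light effects formed a family of their own. List p-values below are these adjusted camera values.

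The alternatives were TMM or quantile rescaling, voom, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, no filter or a minimum of 50, pseudocounts of 0.5 and 5, robust variance moderation, fits of only the 2 groups or of all 24 libraries, the replicate number as a block, each library left out in turn, a 2-fold minimum and an adjusted p under 0.01. Added after the data were seen were a term for the 8 shallow libraries (all monoculture dark libraries and library c of each co-culture light group), leaving out both shallow co-culture light libraries, a block of neighbouring mCherry and GFP columns, and leaving out the monoculture wt dark library with low GC (replicate 1) and the Cry2 dark library with a low RNA integrity number (replicate 3). Left-out-library fits first re-filtered genes; after their first results were seen they were changed to keep the genes of the full fit. Those fits assume that the smaller groups vary as the others do.

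The tests were tried on simulated counts with 50 changed genes of each size. The simulation was first run after the real fits, and now precedes them. Changed genes were drawn only from those with a dark mean of at least 50, so the percentages below do not cover weaker genes. All groups of a culture were simulated with the same mean, apart from the set changes, and the same spread per gene. The real groups differed in spread, and illuminated engineered cells changed many genes. The rates below therefore hold for the simulated setting and need not carry over to the real fits. For wt light against dark (18847 genes) limma found 70% of 1.5-fold, 92% of 2-fold, and 100% of 4-fold and of 8-fold changes, with 5 of 186 calls false. For GFP light against dark (18984 genes) it found 64%, 92%, 100% and 100%, with 8 of 186 false. Chromosome positions of dark differences were examined in 1 Mb windows of at least 5 genes with mean above 500, against 1000 permutations of gene positions. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9 in Python 3.11.15.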

Results

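Transcript levels were measured by RNA sequencing in human embryonic stem cells (line H9) that carried a light-responsive Wnt receptor and in wild-type cells of the same line. The receptor joins Cry2, a plant photoreceptor that clusters under blue light, to the intracellular part of LRP6, a co-receptor of canonical Wnt signalling. The design asks how cells respond when Wnt signalling is switched on by light, and how wild-type cells respond when they grow beside such cells. There were 8 groups of 3 biological replicates: monocultures of Cry2 or wt cells, and mCherry-positive (engineered) and GFP-positive (wild-type) cells sorted from co-cultures, each from dark and light conditions. Assigned reads per library were 28237578 to 34291124 in the dark monocultures, 45763662 to 54707558 in the illuminated monocultures and 31807414 to 56639833 in the co-cultures. Among monoculture libraries, wt dark replicate 1 had a GC content of 33.73% and Cry2 dark replicate 3 had an RNA integrity number of 7.6. Values below are the authors' normalised read counts, as mean ± SD of 3 libraries (n = 3), and adjusted p-values for genes come from limma unless another tool is named; gene lists were tested with camera.

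The first principal component of the 24 libraries held 71.6% of the variance. All 6 illuminated engineered libraries lay at 177.02 to 186.18 on it, and the other 18 lay at -65.10 to -44.12.

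**Figure D1:**
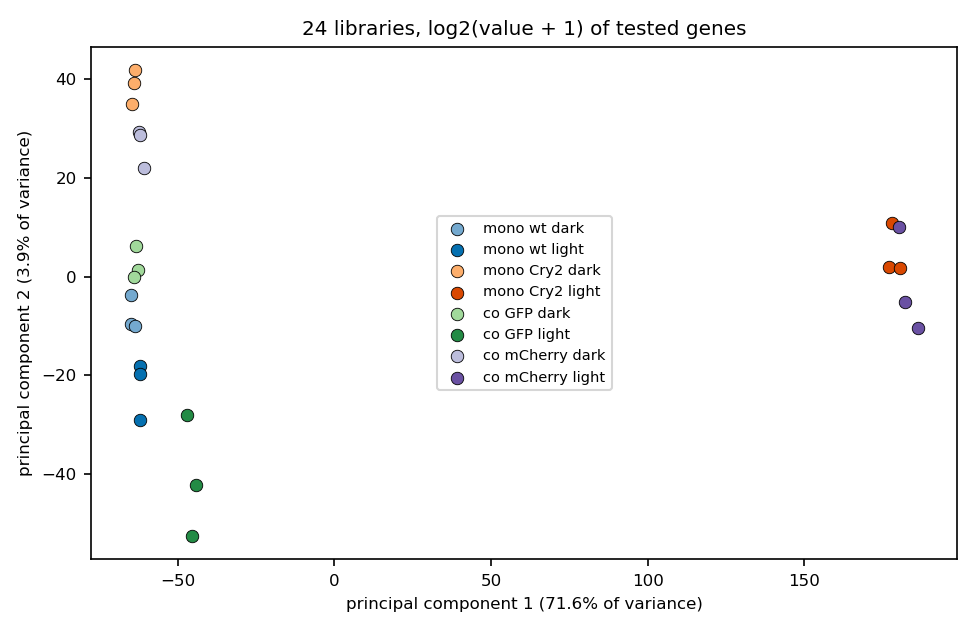
Scores of the 24 libraries on principal components 1 (71.6% of the variance) and 2 (3.9%) of log2(value + 1); each point is 1 library, coloured by group. Illuminated engineered libraries from monoculture and co-culture lie together at the right, and illuminated GFP and wt libraries lie below their dark libraries on component 2.

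The construct was read in the groups that the titles name. The Cry2 fusion stood at 35763 ± 1616 in Cry2 dark, 49395 ± 2041 in Cry2 light, 37014 ± 1051 in mCherry dark and 57087 ± 4646 in mCherry light, and at 271.7 to 396.0 in the mean of each wild-type group. The fusion holds part of LRP6, so reads of the cells' own LRP6 can fall on it, and these low values need not come from the construct. The wt monocultures had no reads of the puromycin gene. The mean of eGFP was 13035 to 14532 in the wild-type groups and 0.5 to 23.3 in the engineered groups. LRP6 (ENSG00000070018; GRCh38 chromosome 12, 12116025 to 12267012, minus strand), which shares sequence with the construct so that its reads are uncertain, was 4.41-fold higher in Cry2 than in wt monocultures (12957 ± 1261 against 2941 ± 602, n = 6 each; exact two-sided permutation p = 0.00216). It was 3.93-fold higher in mCherry than in GFP cells (13482 ± 1827 against 3434 ± 290, n = 6 each; exact two-sided permutation p = 0.00216). In both cultures the 6 engineered libraries lay above all 6 wild-type libraries, and 0.00216 is the smallest p this design allows.

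Under light, Cry2 monocultures raised the transcripts of canonical Wnt targets and of primitive streak and mesoderm regulators, and lowered those of pluripotency factors. AXIN2, a feedback inhibitor of the pathway (chromosome 17, 65528563 to 65561647, minus strand), rose 9.73-fold, from 648 ± 78.2 to 6307 ± 185 (log2 change 3.29 ± 0.09 SE, adjusted p = 1.17e-13). TBXT, the brachyury transcription factor of the streak (chromosome 6, 166157656 to 166168700, minus strand), rose from 5.7 ± 2.81 to 28324 ± 1567 (log2 change 12.12 ± 0.51, adjusted p = 1.43e-11). SOX2, a core pluripotency factor (chromosome 3, 181711924 to 181714436, plus strand), was 237-fold lower, at 38.6 ± 5.91 against 9124 ± 230 (log2 change -7.86 ± 0.09, adjusted p = 3.2e-17). NANOG (chromosome 12, 7787794 to 7799141, plus strand) was 69.6-fold lower (50.9 ± 12.5 against 3544 ± 213), and POU5F1 4.08-fold lower (22407 ± 876 against 91486 ± 5302). In all, 5458 genes rose and 5902 fell among 19444 tested, and 65.7% of genes had no overlap between the groups, where chance gives 10%. All dark libraries were shallower than all light libraries, so depth and light coincide in this comparison.

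Of 15 Wnt/beta-catenin feedback and target genes, 14 rose and none fell, also when adjusted over the list alone (adjusted p = 3.99e-10, adjusted p = 0.00446 with an estimated correlation). LEF1, a transcriptional partner of beta-catenin, rose 995-fold, the feedback inhibitor NKD1 93.2-fold and the TCF factor TCF7 10.3-fold. SP5 and the secreted antagonist DKK1 rose from 2.71 ± 2.18 and 1.93 ± 1.68 to 11400 ± 475 and 46682 ± 1976. Wnt ligand genes rose in 7 of 8 cases, also over the list alone (adjusted p = 3.97e-05, adjusted p = 0.0116 with an estimated correlation): WNT3 14.9-fold, WNT5A 244-fold and WNT3A 359-fold. LRP6 itself stood at 14017 ± 561 against 11897 ± 537 (log2 change 0.24 ± 0.15, adjusted p = 0.185).

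The primitive streak and mesendoderm list had 10 of 12 members higher and 1 lower (adjusted p = 1.99e-06, adjusted p = 0.0066 with an estimated correlation), and the paraxial and posterior mesoderm list 11 of 12 higher and none lower (adjusted p = 1.82e-08, adjusted p = 0.00472 with an estimated correlation). MIXL1 rose 1220-fold and EOMES 614-fold. TBX6, a regulator of paraxial mesoderm, rose 106-fold. MESP1 and HAND1, factors of cardiac and lateral mesoderm, reached 1253 ± 109 and 1874 ± 305 from 2 reads and 1 read over the dark libraries. MSGN1, EVX1 and HOXB3, without reads in the dark, rose at least 8610-fold, 7350-fold and 5210-fold, and the apelin receptor gene APLNR rose 9830-fold to 144680 ± 3549. The streak member that fell was NODAL, a TGF-beta ligand (457 ± 38.3 against 768 ± 89.0; log2 change -0.74 ± 0.13, adjusted p = 0.000124). With a term for shallow libraries its change was 0.219 (adjusted p = 0.574), but the size of that term came only from co-culture light libraries. The value of 0.219 therefore does not measure an effect of depth in monoculture. Of 9 lateral and cardiac mesoderm genes, 7 rose, PDGFRA 198-fold among them, and 1, the troponin gene TNNT2, fell 52.7-fold (adjusted p = 0.0125, adjusted p = 0.132 with an estimated correlation). Of 8 definitive endoderm genes, 5 rose and 1 fell (adjusted p = 0.0201, adjusted p = 0.157 with an estimated correlation). CXCR4 rose 288-fold and GATA4 604-fold, while FOXA2 stayed near the floor at 1.41 ± 0.89 against 3.31 ± 2.19 (adjusted p = 0.206). SOX17 and PAX6 were below the minimum for testing.

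Of 12 pluripotency genes, 11 fell and 1 rose (adjusted p = 3.1e-08, adjusted p = 0.00446 with an estimated correlation). TDGF1, a NODAL co-receptor, was 8.25-fold lower and DPPA4 5.85-fold lower, while SALL4 was 1.57-fold higher. Naive pluripotency genes fell in 5 of 6 cases (adjusted p = 0.0106, adjusted p = 0.0695 with an estimated correlation), TFCP2L1 by 52.3-fold, and all 3 germ cell genes fell (adjusted p = 0.0354, adjusted p = 0.126 with an estimated correlation), TFAP2C by 12.5-fold. Epithelial junction genes fell in 13 of 14 cases and rose in 1 (adjusted p = 2.01e-08, adjusted p = 0.00446 with an estimated correlation). CDH1, the E-cadherin gene, was 13.2-fold lower at 889 ± 98.4 against 11736 ± 187, the splicing regulator ESRP2 46.8-fold lower and the claudin gene CLDN7 12.8-fold lower, while the desmosomal DSP was 3.47-fold higher. All 12 mesenchymal and EMT genes rose (adjusted p = 7.71e-11, adjusted p = 0.00446 with an estimated correlation), among them CDH2 (N-cadherin, 8.33-fold), SNAI1 (40.7-fold), SNAI2 (61.4-fold), CDH11 (85.4-fold) and VIM (16.2-fold). For these lists the counts adjusted over the list alone were the same.

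Signalling and stress lists moved too. In the BMP pathway 10 of 12 genes rose and 1 fell (adjusted p = 9.72e-05, adjusted p = 0.0135 with an estimated correlation): the ligand gene BMP4 rose 78.5-fold, ID3 5.66-fold and ID2 5.24-fold, and BMP7 was 2.43-fold lower. In the Notch pathway 7 of 9 rose and 2 fell (adjusted p = 0.00851, adjusted p = 0.106 with an estimated correlation); the ligands DLL1 and DLL3 rose 21.9-fold and 35.3-fold, and NRARP and JAG1 fell. In the immediate early and heat shock list 10 of 13 rose and 1 fell (adjusted p = 0.000627, adjusted p = 0.146 with an estimated correlation), and in the hypoxia and glycolysis list 7 of 10 rose and 2 fell (adjusted p = 0.0472, adjusted p = 0.129 with an estimated correlation). EGR1 rose 19.5-fold and PDK1 12.1-fold, while VEGFA was 3.67-fold and ADM 32.9-fold lower. Of the 11 p53 targets 8 fell and 1 rose, 9 and 1 over the list alone (adjusted p = 0.0108, adjusted p = 0.175 with an estimated correlation); CDKN1A was 2.83-fold and GDF15 4.61-fold lower. The unfolded protein and amino acid response had 6 of 8 genes lower and 2 higher (adjusted p = 0.0109, adjusted p = 0.18 with an estimated correlation); CHAC1 was 6.28-fold lower and the chaperone gene HSPA5 1.44-fold higher.

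The other 9 lists did not pass in Cry2 monocultures. Rises and falls were 3 and 1 of 5 for neural ectoderm (adjusted p = 0.425), 3 and 2 of 6 for neural crest (adjusted p = 0.699), 2 and 3 of 5 for amnion and surface ectoderm (adjusted p = 0.347), and 2 and 1 of 5 for endothelium and blood (adjusted p = 0.564, the test pointing up with a median log2 change of -0.357). They were 2 and 6 of 9 for NODAL/TGF-beta (adjusted p = 0.199), 6 and 2 of 11 for FGF/ERK (6 and 3 over the list alone, adjusted p = 0.199), and 8 and 4 of 14 for Eph receptors and ephrins (8 and 5 over the list alone, adjusted p = 0.261). They were 3 and 2 of 13 for proliferation (adjusted p = 0.529) and 1 and 6 of 7 for oxidative stress (adjusted p = 0.056). The NODAL feedback inhibitor LEFTY2 was 139-fold lower (2.65 ± 3.29 against 368 ± 34.8), the growth factor gene FGF2 8.0-fold lower and EPHA1 7.46-fold lower, while EPHA4 was 26.5-fold higher.

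**Figure D2:**
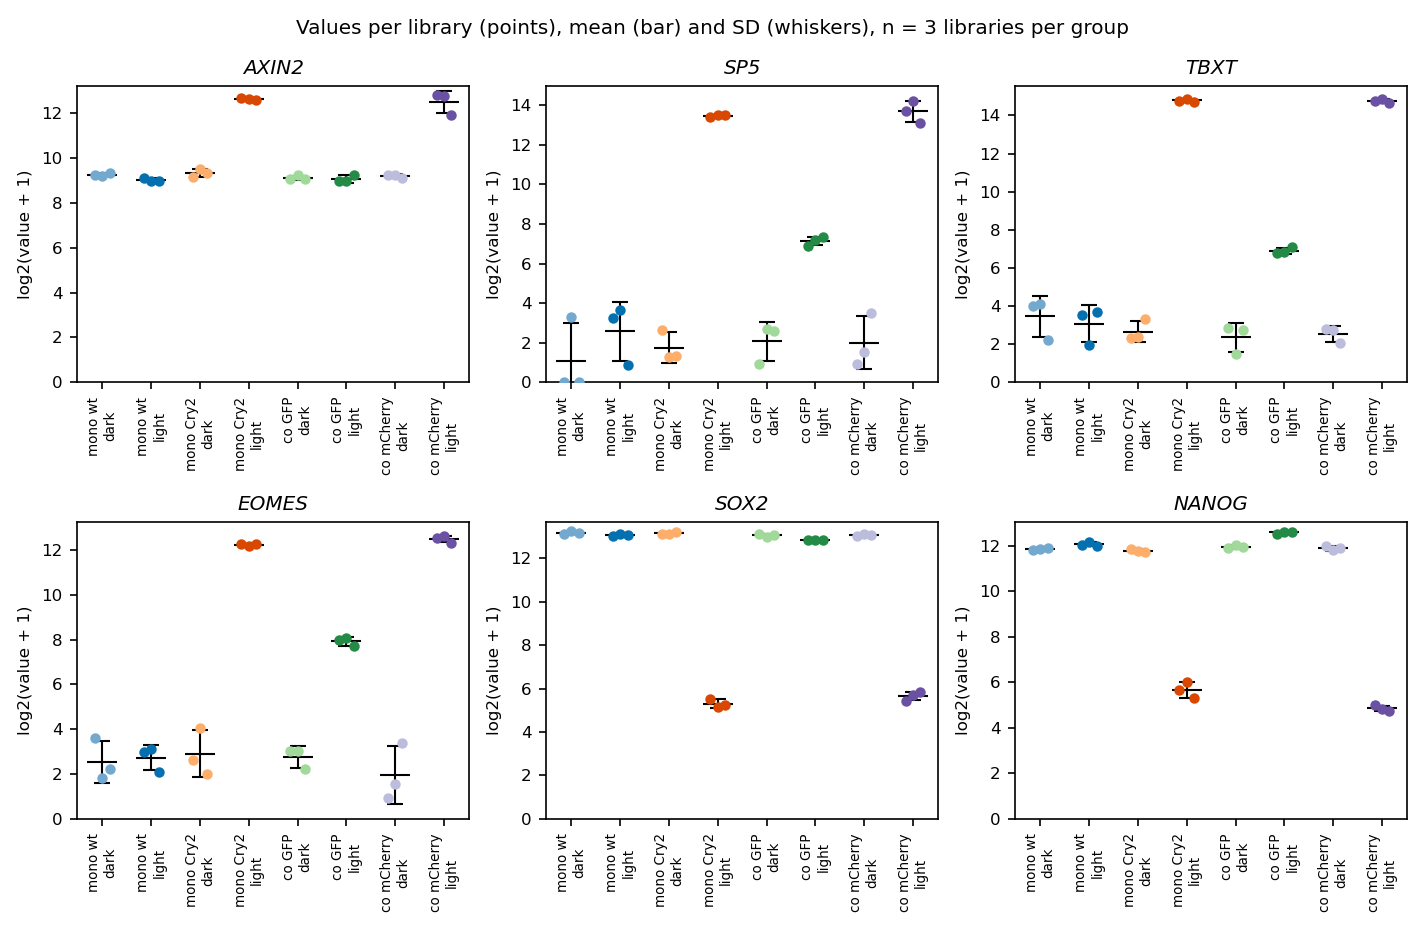
log2(value + 1) of AXIN2, SP5, TBXT, EOMES, SOX2 and NANOG in the 8 groups; points are libraries, bars the group mean and whiskers the SD (n = 3). AXIN2 is high in the illuminated engineered groups (means 6307 and 6045), and EOMES, TBXT and SP5 also lie above the dark level in GFP light (244, 119 and 141).

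Light had a small effect on wt monocultures, the control for illumination itself. The BMP target ID3 rose from 5067 ± 139 to 7046 ± 524 (log2 change 0.47 ± 0.06, adjusted p = 0.00884), and the splicing kinase gene CLK1 fell from 1528 ± 118 to 845 ± 82.0 (log2 change -0.86 ± 0.09, adjusted p = 0.00102). Genes that rose also included the ERK phosphatases DUSP5 (0.56) and DUSP6 (0.40), the early response gene IER2 (0.49), CDC42EP2 (0.62) and the heat shock co-chaperone DNAJB1 (0.40), as log2 changes. Genes that fell included LRIG2 (-0.75), H6PD (-0.68), the acetate enzyme ACSS2 (-0.63, adjusted p = 0.000964), ZNF721 (-0.61), PRICKLE1 (-0.56), the cold-inducible RBM3 (-0.48) and NEDD9 (-0.48). These 14 genes (6 up, 8 down) were all that passed of 19444; none reached 2-fold by limma, 2559 genes lay under an unadjusted p of 0.05 where 972 would by chance, and edgeR called 47. Groups did not overlap for 17.8% of genes, against 10% by chance. In the BMP pathway 1 of 12 genes rose, 3 over the list alone (adjusted p = 0.000362, adjusted p = 0.0174 with an estimated correlation). In the immediate early and heat shock list 2 of 13 rose, 4 over the list alone (adjusted p = 9.52e-05, adjusted p = 0.111 with an estimated correlation). The unfolded protein response had 0 of 8 past the limma threshold, 4 up over the list alone (adjusted p = 0.000494, adjusted p = 0.104 with an estimated correlation), and NODAL/TGF-beta 0 of 9, 1 up over the list alone (adjusted p = 0.0228, adjusted p = 0.146 with an estimated correlation). Wnt targets had 0 of 15 past it, 1 up and 3 down over the list alone (adjusted p = 0.88, the test pointing down with a median log2 change of 0.055), and LRP6 was 2645 ± 719 against 3238 ± 353 (adjusted p = 0.367). Light replicate 2 stood apart in its read counts. They differed from those of replicates 1 and 3 by 56.79 and 46.7 times the chi-square expected per degree of freedom, against 5.66 between replicates 1 and 3. The count of 14 genes was 24 without light replicate 1, 32 without light replicate 2, and 3 without dark replicate 1 or dark replicate 2. Without the low-GC dark library and the Cry2 dark library of low RNA integrity it was 2, and no BMP or immediate early gene passed limma.

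Without light, Cry2 and wt monocultures differed in a set of genes that were close to silent in one line. PUS7L (chromosome 12, 43718993 to 43758817, minus strand) was at least 296-fold higher in Cry2 cells (379 ± 59.0, no reads in wt), and IRAK4, a kinase of Toll-like receptor signalling whose gene starts 126 bases away (43758944 to 43789543, plus strand), stood at 181 ± 6.6 against 1 read over the wt libraries. ZNF736 and the complement receptor-like gene CR1L were at least 192-fold and 87.1-fold higher, and the metallothionein MT1H was 43.0-fold higher. THUMPD3 (chromosome 3, 9362842 to 9386791, plus strand) was 166-fold lower (9.48 ± 8.08 against 1575 ± 39.9; log2 change -7.55 ± 0.40, adjusted p = 6.08e-08), CCDC169 24.5-fold lower, and ZNF502 had 1 read against 187 ± 12.6. The endoderm factor FOXA2 was 12.5-fold lower (3.31 ± 2.19 against 41.4 ± 4.87, with 7 reads over the Cry2 libraries), while BMP4 was 1.85-fold and NODAL 1.40-fold higher (limma adjusted p = 0.0493 for NODAL). Between mCherry and GFP cells in dark co-cultures, FOXA2, BMP4 and NODAL did not pass. In all, 441 genes were higher and 259 lower of 19444, and 27.4% of genes did not overlap between the groups, against 10% by chance. The replicates are cultures, so their spread does not measure variation between independently derived lines. The wt cells also carried transcripts of eGFP and of the neomycin gene (means 14532 and 515.7 in the dark). An effect of the construct can therefore not be told from another difference between the Cry2 and wt cells.

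Transcripts of p53 targets and of the unfolded protein response were higher in Cry2 cells in the dark, while the oxidative stress (adjusted p = 0.308), immediate early and heat shock (adjusted p = 0.684) and hypoxia (adjusted p = 0.17) lists did not pass. Of the 11 p53 targets, 8 were higher and none lower, 10 and 1 over the list alone (adjusted p = 6.39e-11, adjusted p = 0.00784 with an estimated correlation). CDKN1A, the p21 cell cycle inhibitor, was 2.31-fold higher (2480 ± 239 against 1073 ± 90.7; log2 change 1.21 ± 0.10, adjusted p = 5.64e-06), GDF15 2.56-fold, ZMAT3 1.72-fold and the p53 ligase gene MDM2 1.42-fold. The unfolded protein and amino acid response had 4 of 8 higher, 6 over the list alone (adjusted p = 2.01e-08, adjusted p = 0.0171 with an estimated correlation), with DDIT4 2.01-fold and CHAC1 1.58-fold higher. EMT genes were higher in 3 of 12 cases, 4 over the list alone (adjusted p = 0.00603, adjusted p = 0.0491 with an estimated correlation), VIM by 1.25-fold, and proliferation genes lower in 1 of 13, MCM2 (8489 ± 182 against 10180 ± 440; adjusted p = 0.00271, adjusted p = 0.0411 with an estimated correlation). Wnt targets were lower in 1 of 15 cases, APCDD1, and in 2 over the list alone (adjusted p = 0.457); streak genes were higher in 1 of 12 (adjusted p = 0.808) and pluripotency genes higher in 1 and lower in 1 of 12 (adjusted p = 0.582). Both groups held a library that stood apart, wt dark replicate 1 by GC content and Cry2 dark replicate 3 by RNA integrity. By read counts neither did. The chi-square per degree of freedom was 4.51 and 4.48 for wt dark 1, against 5.24 between replicates 2 and 3. For Cry2 dark 3 it was 5.32 and 5.41, against 5.32 between replicates 1 and 2. Without both libraries, and so in smaller groups, 265 genes passed. Among them 5 p53 targets and 4 unfolded protein response genes were higher, and no EMT or proliferation gene passed limma. The count of 700 was 330, 404 and 408 without Cry2 dark replicates 1, 2 and 3, and 401, 405 and 347 without wt dark replicates 1, 2 and 3, but 2470 when only these 2 groups were fitted.

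Under light, Wnt target transcripts were higher and pluripotency transcripts lower in Cry2 than in wt monocultures. AXIN2 was 12.2-fold higher (6307 ± 185 against 519 ± 33.5), WNT3 18.3-fold and BMP4 138-fold, while SOX2 was 226-fold lower and NANOG 84.8-fold lower (51 ± 12.5 against 4318 ± 255). TBXT was 28324 ± 1567 against 8.52 ± 4.95 (log2 change 11.72 ± 0.51, adjusted p = 2.12e-11), and EVX1 and HOXB1 were at least 12400-fold and 9090-fold higher. CDH1 was 13.2-fold lower, CDH2 9.01-fold higher and LRP6 5.30-fold higher. Of 19444 genes 5749 were higher and 6086 lower, and 64.7% did not overlap, against 10% by chance. All 15 Wnt targets were higher (adjusted p = 1.39e-10, adjusted p = 0.00446 with an estimated correlation), as were 11 of 12 streak genes, 1 being lower (adjusted p = 1.05e-06, adjusted p = 0.00594), with 11 of 12 pluripotency genes (adjusted p = 3.15e-08, adjusted p = 0.00446) and 13 of 14 epithelial genes (adjusted p = 1.55e-08, adjusted p = 0.00446) lower. In these lists the counts over the list alone were equal, and 15 lists passed, of which 8 held with an estimated correlation.

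The test of the difference between the light effects of Cry2 and wt monocultures called 9303 genes, with 4433 light effects more positive in Cry2 cells and 4870 more negative. The difference was 3.52 ± 0.13 for AXIN2 (adjusted p = 8.19e-12), 12.51 ± 0.71 for TBXT, 3.64 ± 0.23 for WNT3, -7.76 ± 0.12 for SOX2 and -6.32 ± 0.18 for NANOG, on the log2 scale. For LRP6 it was 0.56 ± 0.21 (adjusted p = 0.0371). All 15 Wnt targets and all 12 EMT genes had a more positive effect (adjusted p = 2.21e-11 and 2.18e-12; adjusted p = 0.00125 and 0.00117 with an estimated correlation). Of 12 pluripotency genes 11 had a more negative and 1 a more positive effect (adjusted p = 1.13e-09, adjusted p = 0.00155 with an estimated correlation), and the counts over the list alone were the same.

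**Figure D3:**
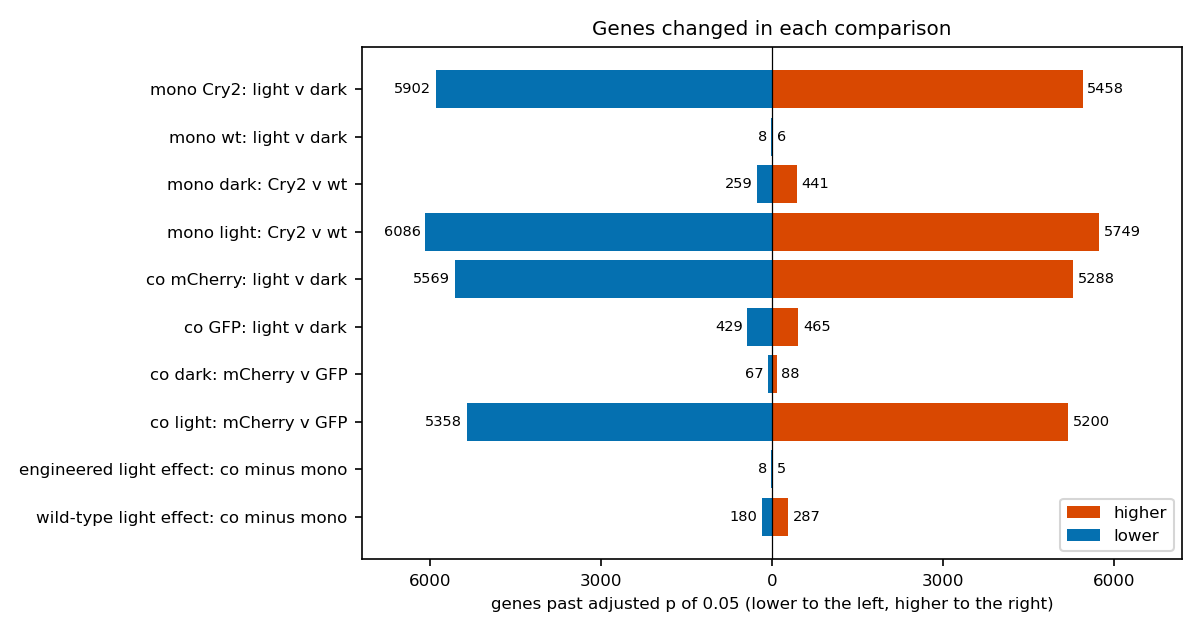
Genes past an adjusted p of 0.05 in each comparison (bars: lower to the left, higher to the right; limma). Engineered cells under light stand out with 10558 to 11835 genes, illuminated GFP cells change 894 genes and illuminated wt monocultures 14.

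Engineered cells sorted from co-cultures responded to light in much the same genes. AXIN2 rose 10.2-fold (6045 ± 1849 against 595 ± 31.4; log2 change 3.29 ± 0.18, adjusted p = 6.43e-10), LEF1 648-fold, NKD1 87.5-fold, MIXL1 1710-fold, TBX6 126-fold, WNT3 15.8-fold and BMP4 75.3-fold. TBXT rose from 4.91 ± 1.53 to 27766 ± 2263, EOMES from 4.07 ± 4.72 to 5786 ± 581, SP5 from 4.33 ± 5.18 to 13841 ± 4947 and DKK1 from 5.98 ± 6.69 to 53845 ± 19339. MESP1 rose 162-fold, SNAI1 33.6-fold, SNAI2 92.0-fold and CDH2 9.10-fold, and EVX1 and HAND1, without reads in the dark, at least 12400-fold and 1990-fold. SOX2 was 173-fold lower (49.6 ± 6.9 against 8562 ± 283), NANOG 138-fold (27.9 ± 2.58 against 3843 ± 280), POU5F1 3.51-fold, CDH1 19.9-fold and LEFTY2 287-fold lower, and the pluripotency-associated FOXD3 at least 586-fold lower. In mCherry light eGFP stood at 23.3, against 13259 in GFP light. Transcripts of GFP cells may thus make up part of the lowest of these values, which was not tested. NODAL was 513 ± 406 against 821 ± 61.0 (log2 change -0.95 ± 0.34, adjusted p = 0.0259), FOXA2 3.18 ± 2.4 against 11.6 ± 4.66 (adjusted p = 0.0199), and LRP6 1.27-fold higher (adjusted p = 0.0025). The fall of NODAL did not hold in every library: the shallow mCherry light library c lay above the dark mean, and a and b below it. SOX17 and PAX6 were again below the minimum for testing.

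In all, 5288 genes rose and 5569 fell in mCherry cells among 19436 tested, and 58.4% of genes did not overlap between light and dark, against 10% by chance. Of genes tested in both cultures (19020), 4582 rose in both engineered populations where independent lists would share 1487.5, and 4893 fell in both where 1671.1 would be shared; 1 and 2 moved in opposite directions. Log2 changes across genes correlated with Pearson's r of 0.965 and Spearman's rho of 0.907, genes not being independent replicates; the cultures share no library. Wnt targets rose in 13 of 15 cases (adjusted p = 2.78e-10, adjusted p = 0.00825 with an estimated correlation), streak genes in 10 of 12 with 1 lower (adjusted p = 2.78e-07, adjusted p = 0.01), EMT genes in 12 of 12 (adjusted p = 9.38e-11, adjusted p = 0.00784) and Wnt ligands in 7 of 8 (adjusted p = 1.32e-05, adjusted p = 0.0174). Pluripotency genes fell in 11 of 12 cases with 1 higher (adjusted p = 2.66e-07, adjusted p = 0.00495 with an estimated correlation) and epithelial genes in 12 of 14 with 1 higher (adjusted p = 9.72e-09, adjusted p = 0.00446). Counts over the list alone were equal for these lists, and 14 lists passed, of which 8 held with an estimated correlation.

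The test of the difference between the engineered light effects of co-culture and monoculture called 13 genes of 20322 (5 more positive and 8 more negative in co-culture). NANOG fell further in co-culture, by a difference of -0.94 ± 0.16 on the log2 scale (adjusted p = 0.0197), as did the growth factor gene FGF19 (-1.21 ± 0.17, adjusted p = 0.00755), TRIM22 (-0.93), FGFBP3 (-0.62), MYLIP (-0.61) and TRBC2 (-2.13). The ERK phosphatase DUSP6 differed by -0.62 and GPR141, near the floor, by -3.69. Effects were more positive for HIVEP3 (2.18), the ciliary factor FOXJ1 (1.48), STC1 (0.99), ESYT2 (0.70) and ZIC5 (0.58); for LRP6 the difference was 0.11 ± 0.18 (adjusted p = 0.972). Under an unadjusted p of 0.05 lay 1018 genes, where chance gives 1016. Epithelial junction genes had 0 of 14 past limma and 4 more negative over the list alone (adjusted p = 3.87e-06, adjusted p = 0.00125 with an estimated correlation). Amnion genes had 0 of 6 and 1 more negative over the list alone (adjusted p = 0.00516, adjusted p = 0.0682 with an estimated correlation), and EMT genes 0 of 12 and none over the list alone (adjusted p = 0.0392, adjusted p = 0.16 with an estimated correlation). The count was 80 and 21 without mCherry light a and c, 2, 4 and 0 without mCherry dark a, b and c, 6 and 20 without Cry2 light 1 and 2, and 8, 2 and 1 without Cry2 dark 1, 2 and 3; it was 8 by edgeR.

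Wild-type GFP cells beside illuminated engineered cells raised primitive streak, BMP and NODAL pathway genes. EOMES (chromosome 3, 27715949 to 27722711, minus strand) rose 41.0-fold, from 5.95 ± 2.05 to 244 ± 32.8 (log2 change 5.18 ± 0.47, adjusted p = 8.96e-06), and TBXT 26.0-fold, from 4.57 ± 2.42 to 119 ± 14.2. The ligand gene WNT3 (chromosome 17, 46762506 to 46833154, minus strand) rose 7.75-fold, from 137 ± 10.9 to 1064 ± 104 (log2 change 2.94 ± 0.12, adjusted p = 5.82e-09). NODAL rose 2.90-fold (1528 ± 102 against 527 ± 11, adjusted p = 0.0163), MIXL1 3.25-fold and NANOG 1.55-fold (6193 ± 189 against 4006 ± 218, adjusted p = 0.000757). For MIXL1, 0.131% of the level in mCherry light, the upper limit of mCherry transcripts in GFP libraries, equals 80.8% of the shift. Genes that fell included the neuronal pentraxin NPTX1 (39.1-fold lower, 29.1 ± 12.6 against 1137 ± 62.6), the cytokine IL17C (57.8-fold), ATP10B (22.8-fold), CUZD1 (11.4-fold) and the stress gene GADD45G (34.8 ± 1.65 against 382 ± 19.8). Genes that rose also included SEZ6L (21.4-fold), the homeobox gene MSX2 (19.0-fold), SAMD11 (15.7-fold) and the cadherin CDH6 (14.1-fold). Of 19436 genes, 465 rose and 429 fell, and 24.8% did not overlap between light and dark, against 10% by chance. LRP6 stood at 3370 ± 432 against 3498 ± 102 (log2 change -0.06 ± 0.08, adjusted p = 0.799).

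Of 12 streak genes 7 rose and none fell in GFP cells (adjusted p = 2.39e-12, adjusted p = 0.00446 with an estimated correlation). The 7 include MIXL1 and EVX1, for which the upper limit of mCherry transcripts equals 80.8% and 432% of the shift. The BMP pathway had 8 of 12 higher and 1 lower, 9 and 1 over the list alone (adjusted p = 2.39e-12, adjusted p = 0.00446 with an estimated correlation): the inhibitors of differentiation ID2, ID3 and ID4 rose 5.22-fold, 4.45-fold and 6.12-fold, and the ligand gene BMP2 was 2.37-fold lower. The NODAL/TGF-beta pathway had 6 of 9 higher and 1 lower (adjusted p = 3.4e-08, adjusted p = 0.00495 with an estimated correlation), with GDF3 up 3.95-fold and the feedback inhibitor SMAD7 2.54-fold. Hypoxia and glycolysis genes rose in 4 of 10 cases, 6 over the list alone (adjusted p = 5.38e-08, adjusted p = 0.00446 with an estimated correlation), PDK1 by 3.06-fold and the glucose transporter SLC2A1 by 1.94-fold. The p53 targets fell in 3 of 11 cases, 5 over the list alone (adjusted p = 5.03e-05, adjusted p = 0.0116 with an estimated correlation), GDF15 by 3.68-fold and CDKN1A by 1.83-fold.

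Other lists were called in GFP cells with the preset correlation only. Wnt targets rose in 5 of 15 cases, with 6 up and 2 down over the list alone (adjusted p = 0.0109, adjusted p = 0.169 with an estimated correlation). SP5 rose 37.4-fold, NOTUM 3.71-fold, BAMBI, also a BMP target, 3.43-fold, LEF1 1.78-fold and TCF7 1.56-fold; AXIN2 did not pass (538 ± 65.3 in light). For LEF1 that upper limit of mCherry transcripts equals 126% of the shift. Definitive endoderm genes rose in 2 of 8, 4 over the list alone (adjusted p = 0.0239, adjusted p = 0.104 with an estimated correlation), CER1 by 2.95-fold and HHEX by 6.89-fold. Pluripotency genes rose in 3 of 12 with 1 lower, 5 and 1 over the list alone (adjusted p = 0.0111, adjusted p = 0.0667 with an estimated correlation): NANOG, PRDM14 and the methyltransferase DNMT3B rose and TDGF1 fell. EMT genes rose in 2 of 12, 3 over the list alone (adjusted p = 0.0119, adjusted p = 0.175 with an estimated correlation), CDH2 by 1.41-fold. Immediate early genes rose in 3 of 13, with 7 up and 1 down over the list alone (adjusted p = 0.000531, adjusted p = 0.119 with an estimated correlation), and Eph receptors and ephrins in 1 of 14, 2 over the list alone (adjusted p = 0.00552, adjusted p = 0.178 with an estimated correlation). Amnion genes rose in 2 of 6 and fell in 2 (adjusted p = 0.744): TFAP2A and GATA3 rose and GABRP and KRT7 fell. Wnt ligands rose in 2 of 8, 3 over the list alone (adjusted p = 0.14), with a median log2 change of -0.089 although the test pointed up. Library c of GFP light was shallow; without it and the shallow mCherry library, 7 streak, 8 BMP, 6 NODAL/TGF-beta and 5 hypoxia genes were higher and 3 p53 targets lower. The count of 894 was 501 and 563 without GFP light b and c, and 572, 485 and 484 without GFP dark a, b and c, but 1356 when only these 2 groups were fitted.

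The GFP response differed from that of wt cells in monoculture. The test of the difference called 467 genes (287 more positive and 180 more negative in co-culture, of 20322). The difference was 5.00 ± 0.74 for EOMES (adjusted p = 0.000175), 4.92 ± 0.63 for TBXT, 2.69 ± 0.20 for WNT3 (adjusted p = 5.82e-09), 1.75 ± 0.29 for MIXL1, 1.47 ± 0.39 for NODAL and 0.63 ± 0.10 for CDH2, on the log2 scale. In wt monocultures EOMES stood at 5.9 ± 2.37 in light and 5.74 ± 4.6 in the dark, TBXT at 8.52 ± 4.95 and 11.7 ± 6.91, and WNT3 at 151 ± 38.5 and 124 ± 4.02. Effects were also more positive for ID1 (2.55), ID4 (2.53), ID2 (1.68) and ID3 (1.68), and more negative for IL17C (-5.28), NPTX1 (-4.78) and GADD45G (-3.02). Streak genes were more positive in 7 of 12 cases (adjusted p = 1.94e-11, adjusted p = 0.000229 with an estimated correlation), BMP genes in 6 with 1 more negative, 7 and 1 over the list alone (adjusted p = 1.58e-09, adjusted p = 0.000433), and NODAL/TGF-beta genes in 5 with 1 more negative, 6 and 1 over the list alone (adjusted p = 2.4e-06, adjusted p = 0.00318). Hypoxia genes were more positive in 4 of 10 (adjusted p = 3.4e-07, adjusted p = 0.00109 with an estimated correlation) and p53 targets more negative in 2 of 11, 4 over the list alone (adjusted p = 0.000126, adjusted p = 0.00318). The difference for LRP6 was 0.26 ± 0.18 (adjusted p = 0.582). Without GFP light b and c the count was 311 and 305, without GFP dark b and c 271 and 292, and without wt dark 2 it was 289.

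Genes that changed with light in GFP cells overlapped those of the mCherry cells, with which they grew, in both directions. Of the 465 that rose in GFP cells, 286 also rose in mCherry cells, where independent lists would share 126.5, and 114 fell (133.2). Of the 429 that fell, 297 also fell (122.9) and 68 rose (116.7). Across genes the log2 changes correlated with r of 0.280 and rho of 0.262. If both kinds of cell were sorted from the same dishes, these lists are not independent, and no expectation that allows for this was computed. Of the 14 genes changed in wt monoculture, 1 of 6 up and 2 of 8 down also changed in the same direction in GFP cells (0.1 and 0.2 from independent lists).

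**Figure D4:**
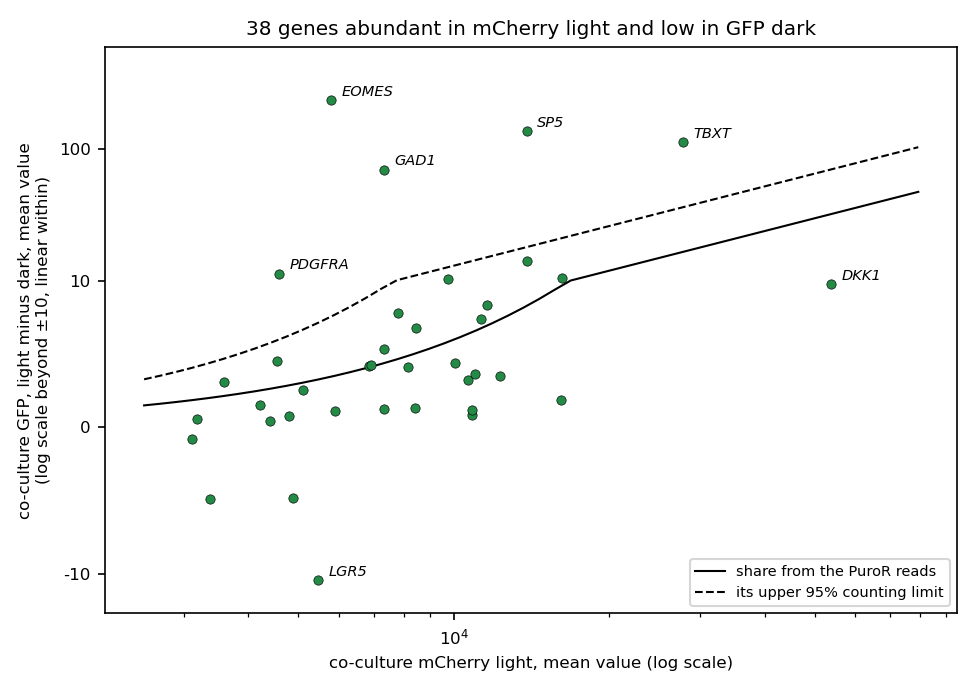
Light minus dark in GFP cells against the level in mCherry light for the 38 genes above 3000 in mCherry light and below 20 in GFP dark; lines show the share of mCherry transcripts given by the PuroR reads (0.06%) and its upper 95% counting limit (0.131%). EOMES, SP5, GAD1, TBXT and PDGFRA lie above the upper limit, at 4.11, 0.990, 0.960, 0.411 and 0.249%.

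In the dark, co-cultured mCherry and GFP cells differed in a smaller set of genes, most of which also differed between the monocultures. ZNF736 and IRAK4, without reads in GFP cells, were at least 310-fold and 194-fold higher (255 ± 39 and 160 ± 24), PUS7L 322-fold, CR1L 49.2-fold and MT1H 30.3-fold higher. THUMPD3 was 86.8-fold lower (17 ± 4 against 1451 ± 84.7; log2 change -6.38 ± 0.36, adjusted p = 1.87e-07), CCDC169 55.7-fold lower, and ZNF502 had 1 read against 118 ± 23. The ephrin gene EFNB1 was 1.90-fold higher and PDK1 1.48-fold lower. Of 19436 genes 88 were higher and 67 lower; 16.5% did not overlap, against 10% by chance, and 1098 lay under an unadjusted p of 0.05, where 972 would by chance. Of genes tested in both cultures, 80 of 87 higher ones were also higher in Cry2 monocultures and 57 of 67 lower ones also lower, where independent lists would share 2.0 and 0.9; none was opposite. The monocultures held 441 higher and 256 lower genes among those tested in both. Both cultures set engineered against wild-type cells, so this overlap does not tell a construct effect from another difference between these cells. The p53 targets had 0 of 11 past limma, also over the list alone (adjusted p = 0.0242, adjusted p = 0.104 with an estimated correlation), and the unfolded protein response 0 of 8 (adjusted p = 0.00387, adjusted p = 0.175 with an estimated correlation). The count of 155 was 94 and 96 without mCherry dark b and c, and 101, 95 and 97 without GFP dark a, b and c, but 306 with neighbouring columns as a block and 385 when only these 2 groups were fitted.

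**Figure D5:**
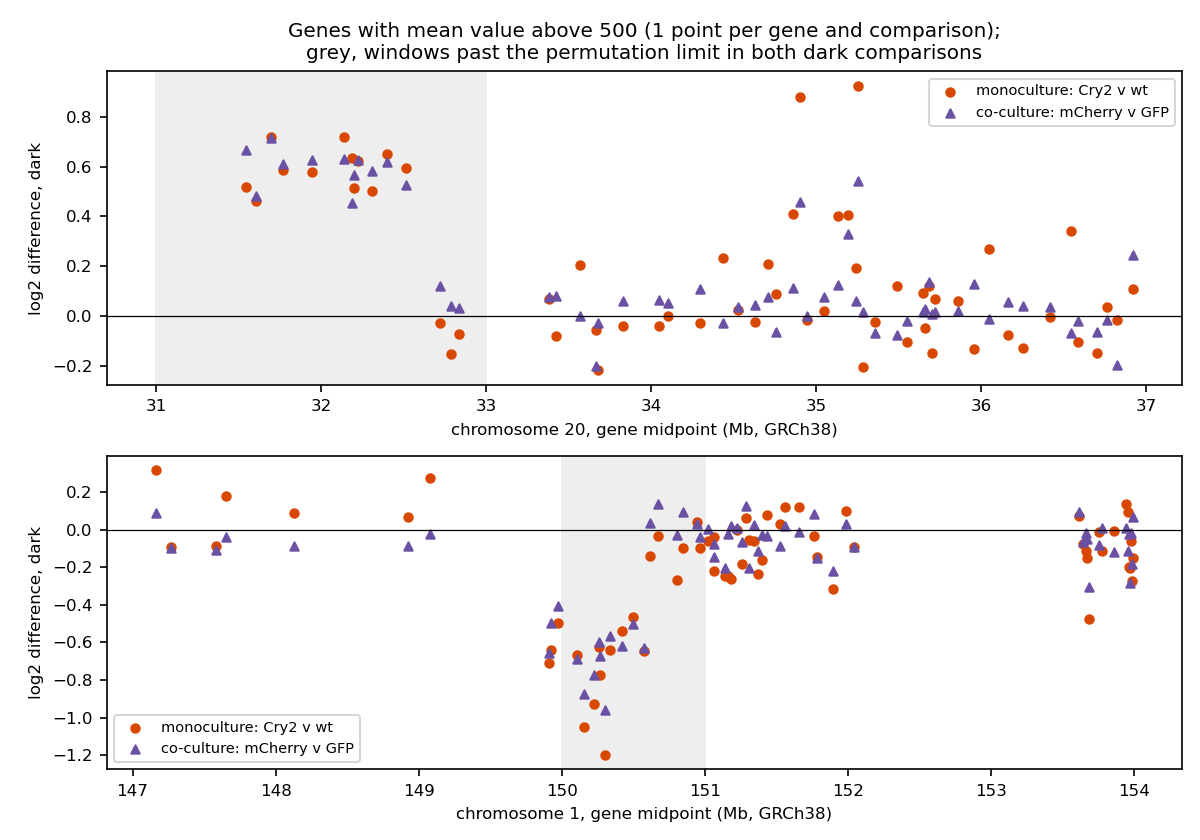
Log2 difference in the dark of engineered against wild-type cells by gene midpoint (Mb) on chromosomes 20 and 1; circles are monoculture, triangles co-culture, 1 point per gene with mean above 500. Medians of the genes in the grey windows are 0.577 and 0.582 on chromosome 20 and -0.583 and -0.582 on chromosome 1 (monoculture and co-culture), while some of these genes, such as DNMT3B and SETDB1, lie near 0.

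In the light, co-cultured mCherry cells differed from their GFP neighbours in Wnt targets and pluripotency genes. AXIN2 was 11.2-fold higher (6045 ± 1849 against 538 ± 65.3), TBXT 234-fold, SP5 98.3-fold, EOMES 23.7-fold and WNT3 2.93-fold (3115 ± 329 against 1064 ± 104). SOX2 stood at 49.6 ± 6.9 against 7437 ± 1.31. NANOG was 222-fold, CDH1 26.1-fold, POU5F1 3.99-fold and NODAL 2.98-fold lower (513 ± 406 against 1528 ± 102, adjusted p = 0.000274). For NODAL the shallow mCherry light library c lay far above a and b, so the size of that difference is uncertain. LRP6 was 4.48-fold higher. Of 19436 genes 5200 were higher and 5358 lower, and 54.1% did not overlap, against 10% by chance. Wnt targets were higher in 14 of 15 cases (adjusted p = 1.75e-10, adjusted p = 0.00797 with an estimated correlation), Wnt ligands in 8 of 8 (adjusted p = 7.89e-06, adjusted p = 0.0171) and EMT genes in 12 of 12 (adjusted p = 8.25e-11, adjusted p = 0.00784). Pluripotency genes were lower in 11 of 12 with 1 higher (adjusted p = 5.38e-08, adjusted p = 0.00446 with an estimated correlation). BMP genes were higher in 5 and lower in 4 of 12 (adjusted p = 0.347), and NODAL/TGF-beta genes higher in 2 and lower in 7 of 9 (adjusted p = 0.0282, adjusted p = 0.126 with an estimated correlation). The test of the difference between the light effects of mCherry and GFP cells called 7880 genes (3798 more positive and 4082 more negative): AXIN2 by 3.35 ± 0.26, TBXT 7.69 ± 0.45, EOMES 5.38 ± 0.66, WNT3 1.03 ± 0.17, NODAL -2.48 ± 0.48, NANOG -7.68 ± 0.13 and LRP6 0.41 ± 0.12 (adjusted p = 0.0124). In that test Wnt targets were more positive in 13 of 15 cases and Wnt ligands in 8 of 8 (adjusted p = 0.00508 and 0.0139 with an estimated correlation), and BMP genes more positive in 4 and more negative in 3 of 12 (adjusted p = 0.252).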

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

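The tests of the difference between light effects were planned, while the splits of the libraries and the tests of explanations in this part were chosen after the result was seen.

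The light effects of groups differed by tests of the difference itself: 9303 genes between Cry2 and wt monocultures, 7880 between mCherry and GFP cells, 13 between engineered cells of co-culture and monoculture, and 467 between wild-type cells of co-culture and monoculture. For engineered cells the difference of NANOG was -0.94. For wild-type cells the differences were 2.69 for WNT3, 1.47 for NODAL, 5.00 for EOMES, 4.92 for TBXT, 0.63 for CDH2 and 1.75 for MIXL1, on the log2 scale. With the libraries regrouped, 4 of 100 splits gave at least 9303 genes (highest other split 9431) and 4 of 100 at least 7880 (highest other 8127), in each case the real split included. These highest other splits exchanged 2 and 3 dark libraries but 0 light ones. They kept the difference between engineered and wild-type cells under light, so these counts of splits do not settle chance. The median other split gave 0 genes in both tests. At least 13 genes came from 5 of 100 splits of the engineered libraries (highest other 1122). For the 467 genes it was 11 of 100 (highest other 1988, a split that exchanged all 3 dark libraries between the cultures). For the 13 genes the highest split exchanged 1 dark and 2 light libraries between the cultures. Such a split also measures the difference between the cultures, so the count of splits does not settle chance. Under an unadjusted p of 0.05 by limma lay 1018 genes, where chance gives 1016. That total does not judge the few smallest p-values, so it does not settle chance for the 13 genes either. Without 1 library at a time their count ran from 0 to 80, and chance stays open for them. For the 467 genes, exchanging all 3 dark libraries measures the difference between the cultures, so that split points to a structure of the samples and the count of splits does not settle chance. Under an unadjusted p of 0.05 by limma lay 2734 genes there, where chance gives 1016.

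For the 8 comparisons of 2 groups of 3, the 10 possible splits are too few to judge chance. The real split gave the most genes in each, 1 of 10 splits: 11360, 700, 11835, 10857, 894, 155 and 10558 genes against 0 in the highest other split, and 14 against 1 for wt light.

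Light changed 894 genes in GFP cells sorted from co-cultures and 14 in wt monocultures. If mCherry cells or their RNA had been carried into the GFP libraries, the puromycin gene, read 6 times there, puts the share of mCherry transcripts at 0.06%, with an upper 95% counting limit of 0.131%. At that limit 888 of the 894 genes had under 50% of their shift accounted for, which speaks against carry-over as their main cause. For the 429 genes that fell and the 217 that rose above mCherry light, so small a share could hardly have given another outcome. A smaller part of the shift of other genes may still come from carry-over. For 6 genes (EVX1, HOXB3, HOXB1, APLNR, LEF1 and MIXL1), named here after their values were seen, carry-over stays open. Against light itself, without engineered neighbours, speak the 387 genes that also passed the test of the difference from monoculture in the same direction, as far as that test between experiments holds, while for 507 it stays open. The shallow library of each co-culture light group is not the whole cause, since 635 genes kept their call and direction without both. A response of wild-type cells to illuminated engineered neighbours remains possible, but co-culture coincides with the experiment, so another difference between the 2 experiments stays open.

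Light changed 11360 genes in Cry2 monocultures, where every dark library was shallower than every light library. A depth difference of the same kind lay between wt dark and light libraries, where 14 genes changed, so depth does not account for the pattern. A few genes taking most of the reads does not either: the highest share of 1 gene in any library was 1.52%. A response to the receptor under light may be the cause, as the engineered cells were the only ones with the construct; 9303 genes passed the test of the difference from wt.

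Construct features were read at low levels outside the cells that carry them, compared with monocultures. The mean of eGFP was 23.3 in mCherry light (69 reads) and 4.8 in mCherry dark (17 reads), against 0.5 in each Cry2 monoculture group. The mean of the puromycin gene was 1.6 in GFP light (6 reads) and 2.5 in GFP dark (10 reads). That of the neomycin gene was 1.0 in mCherry light (3 reads) and 2.4 in mCherry dark (8 reads). Neither gene had reads in the monocultures of the same genotype.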

How the results depend on the processing

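Counts of changed genes stayed within 1.5 times the reported value in 211 alternative fits and moved further in 67; of the tests of LRP6 and the genes chosen beforehand, made for light against dark in Cry2, mCherry and GFP cells, 1483 kept direction and call, 8 were newly called, 36 lost the call and 1 reversed. The reversed value was NODAL in Cry2 light against dark with a term for shallow libraries (0.219, adjusted p = 0.574). Every monoculture dark library is shallow and no monoculture light library is, so monoculture cannot tell that term from light. Its size came only from library c against a and b in the co-culture light groups. For NODAL, mCherry light c lay far above a and b. In monoculture comparisons of light and dark the term thus carries over a difference seen in co-culture, and the reversal does not test depth there. Without 1 library at a time the counts ran, for Cry2 light, from 10570 to 10688; wt light 3 to 32; dark monocultures 330 to 408; light monocultures 10888 to 11786; difference of monoculture light effects 8542 to 9798; mCherry light 9750 to 11808; GFP light 484 to 780; dark co-cultures 94 to 109; light co-cultures 9523 to 11571; difference of co-culture light effects 7050 to 9308; engineered difference 0 to 80; wild-type difference 271 to 495. Smaller groups lower the power of these fits.

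With a 2-fold minimum, which by construction leaves fewer genes, the counts in that order were 5482, 0, 171, 5476, 5005, 5550, 316, 77, 5297, 4700, 5 and 188. Under an adjusted p of 0.01 they were 3 (wt light), 291 (dark monocultures), 424 (GFP light), 97 (dark co-cultures), 1 (engineered difference) and 186 (wild-type difference). With only the 2 groups compared they were 4 (wt light), 2470 (dark monocultures), 1356 (GFP light) and 385 (dark co-cultures). For wt light voom gave 22, edgeR 47, robust moderation 34, the shallow term 38, and the fit without the low-GC and low-integrity libraries 2, which gave 265 for dark monocultures. For the engineered difference voom gave 5, edgeR 8 and the fit without both shallow co-culture libraries 22. Apart from the thresholds and left-out libraries, the cause was not tested. The dark libraries of the monocultures, at 28237578 to 34291124 reads, limit what can be seen of weakly expressed genes.

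Monoculture libraries share replicate numbers only. With the replicate number as a block the counts were 11296, 10, 605, 11800 and 9165, so it moved none by more than 1.5 times; 18 pairs with the same number correlated at -0.003 on average (-0.061 to 0.058), 0 of them above 0.1, against 0.002 for 36 other pairs. Co-culture columns carry no replicate number. In a check added after the data were seen, neighbouring mCherry and GFP columns correlated at 0.288, 0.084 and 0.159 in light and 0.101, 0.008 and 0.091 in the dark, against means of -0.088 and -0.034 for other pairs, a hint of shared dishes. With these pairs as a replicate block the counts were 306 (dark co-cultures), 12283 (light co-cultures) and 9971 (difference of co-culture light effects). No paired analysis was possible for light against dark in co-culture because nothing links those columns.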

Other observations

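Several signalling and pluripotency genes were higher in GFP cells than in mCherry cells of illuminated co-cultures, and above their own dark level. The genes named in this paragraph were chosen after their values were seen. NANOG stood at 4006 in GFP dark, 6193 in GFP light and 27.9 in mCherry light, and the TGF-beta family gene GDF3 at 295, 1164 and 35.7. The BMP target ID1 stood at 1563, 12830 and 4667 (± 4150 over the 3 mCherry libraries), ID4 at 113, 691 and 199, and the feedback inhibitor SMAD7 at 1044, 2657 and 741. The Notch ligand DLL1 and the ligand gene BMP2 ran the other way, at 272, 111 and 6545 and at 112, 47.4 and 5471. Of the 465 genes that rose in GFP cells, 217 had a higher mean in GFP light than in mCherry light. Among all genes called between these 2 groups, 5358 of 10558 were higher in GFP cells. The count of 217 therefore does not set the genes that rose apart.

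TFAP2A, a factor of surface ectoderm and amnion, had no reads in GFP dark and 17.8 ± 2.53 in GFP light (at least 21.6-fold), and GATA3 rose 6.75-fold, while GABRP, of the same list, was 6.5-fold lower. The cadherin CDH6 went from 28.3 to 399 in GFP cells and was 8.22 in mCherry light.

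The tests on the chromosome blocks under light were written before those values were seen; the windows themselves were found from the dark libraries. In the dark, 3 of 717 windows of 1 Mb passed the 95% permutation limit in both cultures (0.378 in monoculture and 0.244 in co-culture): chromosome 20, 31000001 to 32000000 (median log2 difference 0.577 and 0.628) and 32000001 to 33000000 (0.554 and 0.546), and chromosome 1, 150000001 to 151000000 (-0.583 and -0.582). Runs of consecutive genes past 0.4 or below -0.3 in dark co-cultures, limits chosen after the values were seen, were then counted. They held 12 genes on chromosome 20, from HM13 to NOL4L with BCL2L1 and ID1 among them, and 13 on chromosome 1, from SV2A to MCL1. Genes outside these runs also passed the limits, such as ACSS2 (0.459) and MMP24 (0.543) on chromosome 20 and NPR1 (-0.307) on chromosome 1. In dark monocultures all 12 were higher in engineered cells and all 13 lower, though most of them lie in windows picked partly by their monoculture medians.

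A gain of 20q11.21 recurs in cultured human embryonic stem cells, and an extra copy of a block would give a log2 difference near 0.585. If copy number were the cause, the shift would also be present under light: the median of the chromosome 20 block in co-culture light was 0.83 and that of the chromosome 1 block -0.455 over all genes of the windows, both inside the ranges written beforehand (0.3 to 0.9 and -1.2 to -0.3). For the run of 12 genes on chromosome 20, however, the medians under light were 1.052 in co-culture and 1.164 in monoculture, above that range. Losing 1 of 2 copies would give -1, and the chromosome 1 medians lay short of that in the dark too, nearer to 2 copies against 3. Copy number therefore stays open as a possible explanation for both blocks. This is a weak test, since 8 of 717 windows lay as far out as the chromosome 20 block under light and 30 of 717 as far as the chromosome 1 block, with a window SD of 0.474. A regional change of transcription without copy change was not tested, and no DNA was analysed here.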
